A study of Homo sapiens with 6 samples.

How the data were processed

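RNA sequencing had been run on 6 libraries of D283 Med, a cell line grown from a paediatric medulloblastoma, a tumour of the cerebellum. Per the labels, 3 libraries came from wild-type cells (WT) and 3 from cells with knockdown of Musashi-1 (gene MSI1), an RNA-binding protein of neural stem cells. The labels used here do not say how the knockdown was made, whether the WT cells carried a control construct, or whether the 3 libraries of a group came from separate cultures. The p-values therefore measure the spread between these libraries, part of which may be technical.

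Per the labels' protocols, total RNA was extracted with a column kit, its integrity was checked on a Bioanalyzer and libraries were made by a standard Illumina protocol. Per the submitters' processing notes, the tools were CASAVA 1.8.2, Trim Galore, FastQC, MultiQC, STAR and DESeq, and the genome build was GRCh38. The read counter, the annotation, any filter and the use of strand are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical copies, such as ribosomal protein pseudogenes and histone paralogs, may thus have been split or shared between rows. Whether polyadenylated RNA was selected is not given either.

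The deposited table gives 1 log2-like value per gene and library, which the authors had normalised by a size factor per library and put through a variance-stabilising function, going by the file's name and its values. It holds 31785 rows. Of these, 1167 carry only an Ensembl identifier, and 244 rows share 33 names that occur more than once. On this scale differences of abundant genes are close to log2 fold changes, and differences of weakly expressed genes are understated. The columns of the knockdown libraries are headed as knockdown. The other 3 columns have a heading that the labels do not explain, and they were taken as WT by elimination, since 6 columns stand for 6 libraries in 2 groups. No column was left without a library.

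The lowest value, 5.79, is that of a count of 0. Inverting the stabilising function with the offset 55.2 gave normalised read counts, and 100% of the values of each library became whole reads, within a tolerance of 0.01, after multiplication by 1 size factor per library. These recovered reads gave the depth, which was 17299671, 38790342 and 29173018 reads for WT 1, 2 and 3 and 24442276, 18895997 and 23369283 reads for knockdown 1, 2 and 3. Normalised read counts and folds printed for single genes come from the same inversion. They are means ± SD over 3 libraries, and a fold is the ratio of the group means.

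Differences are knockdown minus WT on the deposited scale. Genes were kept where the mean over the 6 libraries was at least 1 above the lowest value, a level of 27.6 normalised reads, which kept 13558 rows and left out 18227. The test was limma 3.58.1 in R 4.3.3 (linear model per gene, empirical Bayes with a mean-variance trend, two-sided), without covariates, and Benjamini-Hochberg adjustment over the kept genes with a threshold of 0.05. An exact permutation test of 3 against 3 libraries cannot give a p below 0.1, so it cannot pass that threshold for any gene. Gene lists were compared with all other genes by limma's camera with a preset correlation of 0.01 between genes, adjusted over the 35 lists with at least 5 kept members out of 38 lists. Counts of list members adjusted over the list alone are given beside those over all genes. The lists held 872 different genes, of which 822 were in the table, partly under older symbols, and 653 were kept.

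The test, the filter, the lists and the rule for naming genes were fixed before the data were examined. The rule names MSI1 and MSI2. It then takes the 10 largest rises and the 10 largest falls among called genes with a symbol, whose groups do not overlap and whose mean lies at least 2 above the lowest value. It adds up to 4 called members of each list past the threshold and up to 2 of each other list. Some genes that the rule takes are not reported here. Genes named outside it are said to be chosen after their values were seen. Alternatives fixed in advance were other filters, scalings and variance models, library weights, the replicate number as a block, a minimum difference of 0.5 (limma treat), each library left out in turn, camera with an estimated correlation, and fry. Alternatives chosen after seeing the data were limma voom on the recovered reads, regression of each library on transcript length and GC content (known for 13370 kept rows), and leaving out the genes of the long arm of chromosome 17. Coordinates are GENCODE 29 on GRCh38, 1-based, matched by gene name, since the authors' annotation is not given in the sources used here.

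On data simulated from the real means, library sizes and spread of this comparison, with 13543 genes in the fit and 50 genes changed at each size, the test recovered 12% of genes changed 1.5-fold, 48% of those changed 2-fold, 82% at 3-fold and 86% at 4-fold. Of the 120 genes called there, 5% had not been changed. Many changes under 2-fold would thus be missed with 3 libraries per group in such a setting. The real comparison had more genes at low p, 2976 at an unadjusted p under 0.05, which loosens the adjusted threshold. Its recovery may therefore differ. Interval statements use a confidence level of 95%.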

Results

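Gene expression was measured by RNA sequencing in D283 Med, a medulloblastoma line assigned by the study to Groups 3 and 4, the subgroups of this tumour without a defining Wnt or hedgehog mutation. The 6 libraries comprised 3 from WT cells and 3 from cells labelled as Musashi-1 knockdown. Depth was 17299671 to 38790342 reads per WT library and 18895997 to 24442276 per knockdown library, and between 22283 and 26344 rows had at least 1 read. The libraries of a group correlated with r of 0.978 to 0.985 in WT and 0.988 to 0.994 in knockdown, across genes. No pair agreed within sampling noise. The first principal component held 42.5% of the variance and separated the groups. The median SD over genes was 0.18 in WT and 0.12 in knockdown on the log2 scale. A single comparison follows from this design, which asks what lowering Musashi-1 does to the transcriptome of these cells.

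MSI1 mRNA was little lower in the libraries labelled knockdown. MSI1, on the minus strand of chromosome 12 at 120341330 to 120369180 (GRCh38), had 1585.7, 1572.3 and 1377.8 normalised reads in the WT libraries and 1385.3, 1197.2 and 1281.2 in the knockdown libraries. The means were 1512 ± 116 and 1288 ± 94.3 (SD, n = 3 each). Knockdown thus held 85.2% of the WT level, with a 95% interval of 72.2% to 102.8% from the model. The difference was −0.21 (SE 0.12) on the log2 scale and did not pass the test (limma, adjusted p = 0.304). Between 952 and 2493 reads lay on the gene in each library, so an mRNA loss of 50% would have been outside the interval. MSI2, the paralog that binds similar RNA motifs, lies on the long arm of chromosome 17 at 57255851 to 57684685. It had 8255 ± 1691 normalised reads in WT and 6202 ± 915 in knockdown (SD, n = 3), 75.1% of WT with a 95% interval of 58.8% to 98.2%. Its difference of −0.40 (SE 0.17) did not pass either (limma, adjusted p = 0.198, range over 16 alternatives 0.0404 to 0.474), except with library weights, where it was −0.54 (adjusted p = 0.0404). The measured genes of that chromosome arm had a median difference of −0.33, and MSI2 lay at percentile 39.1 among them.

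**Figure D1:**
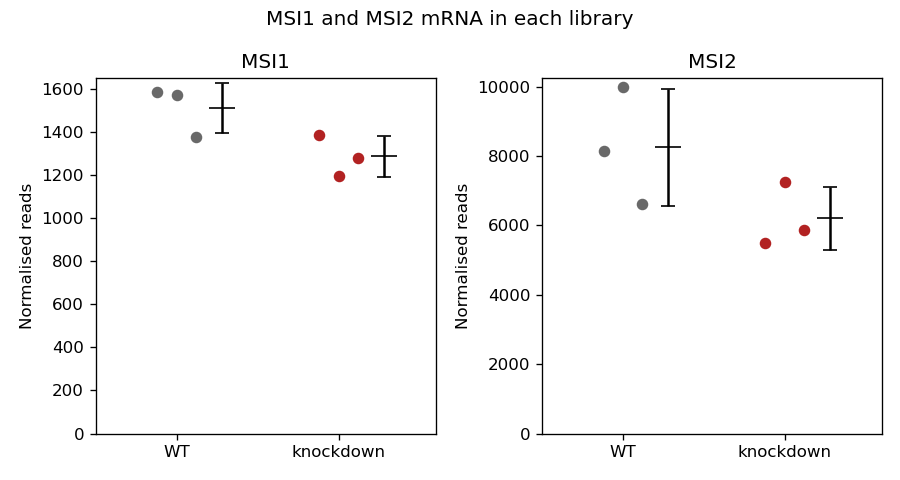
Normalised reads of MSI1 and MSI2 in each library (points), with mean and SD of the 3 libraries of a group beside them. MSI1 in knockdown 1, at 1385.3, lies above WT 3, at 1377.8, so the groups overlap.

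Many other genes differed between the groups. Of 13558 genes tested, 242 rose and 314 fell in knockdown (limma, adjusted p under 0.05), and 72 of these changed by at least 1 on the log2 scale, 30 up and 42 down. At an unadjusted p under 0.05 there were 2976 genes. All 556 called genes had groups that did not overlap, which held for 27.8% of all tested genes against 10% by chance. The typical called gene moved by 0.70 up or −0.69 down (medians). The count depended on single libraries. It was 56, 126 and 92 without knockdown 1, 2 or 3, 204 without WT 2, 498 without WT 3 and 726 without WT 1. Among the genes taken by the naming rule, 41, 34 and 34 lost their call without knockdown 1, 2 or 3, 30 without WT 2, 17 without WT 3 and 8 without WT 1.

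The largest falls included secreted and surface proteins of neural development. RELN, the extracellular glycoprotein reelin, which guides neuronal migration and is made by cerebellar granule cells, fell 3.40-fold, from 2599 ± 1033 to 764 ± 247 normalised reads (SD, n = 3; difference −1.62, SE 0.26, limma adjusted p = 0.0126). SEMA3A, a repulsive axon guidance ligand, fell 3.07-fold, from 4750 ± 1099 to 1548 ± 165 (difference −1.53, SE 0.17, limma adjusted p = 0.00454). CDH2, N-cadherin, fell 2.75-fold from 5022 ± 945 to 1828 ± 392 (−1.41, SE 0.18). GPNMB, a membrane glycoprotein, fell 3.38-fold (−1.60, SE 0.23), and C3, the central complement component, fell 2.85-fold (−1.39, SE 0.22). ANK2, an ankyrin that anchors membrane proteins to the cytoskeleton, fell 3.30-fold, CLIP3 fell 3.80-fold, and HIST1H1C, a linker histone, fell 3.03-fold. GPNMB missed the threshold without knockdown 1 (limma, adjusted p = 0.0552) and C3 without knockdown 2 (0.0521).

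Among the rises, ASS1, argininosuccinate synthase, increased 3.10-fold from 1553 ± 47.7 to 4814 ± 1810 normalised reads (SE of the log2 difference 0.22, limma adjusted p = 0.00821). LOXL4, a lysyl oxidase that cross-links collagen, rose 3.78-fold from 203 ± 47.9 to 769 ± 110 (1.53, SE 0.16, limma adjusted p = 0.00395). MATK, a kinase that inhibits Src family kinases, rose 3.83-fold from 163 ± 37.9 to 623 ± 28.9 (1.49, SE 0.14). SH3GL2, endophilin A1 of synaptic vesicle recycling, rose 3.65-fold (1.40, SE 0.18), and NPS, the neuropeptide S precursor, rose 4.16-fold from 102 ± 43.0 to 424 ± 116 (1.44, SE 0.21). On the deposited scale the rule's largest difference among the rises was that of GSG1, 3.77-fold from 362 ± 248 to 1364 ± 423, with a wide spread in WT (1.77, SE 0.35, limma adjusted p = 0.0273). ADGRF5, an adhesion G protein-coupled receptor, rose 3.82-fold (1.59, SE 0.36), AMER2, a regulator of Wnt signalling, 2.99-fold (1.34, SE 0.31), the long noncoding RNA AC015522.1 3.19-fold (1.34, SE 0.23) and KIAA2012 2.85-fold (1.28, SE 0.30). GSG1, ADGRF5, AMER2 and KIAA2012 lost their call when the variance estimate was made robust (adjusted p = 0.0635, 0.0853, 0.0770 and 0.0813), and over all alternatives they lost it in 4, 5, 6 and 7 of 17. ASS1 and NPS missed the threshold without knockdown 1 (adjusted p = 0.0552 each). AC015522.1 missed it without WT 2 (0.0537) and without knockdown 1, 2 or 3 (0.0683, 0.0670 and 0.0602). LOXL4, MATK, SH3GL2, RELN, SEMA3A, CDH2, CLIP3, ANK2 and HIST1H1C kept theirs in each of 17 alternative fits, including those with each library left out in turn, though not in the test of a minimum difference.

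Cell cycle entry, translation and sterol genes were higher together. Of 35 measured G1/S genes, whose mRNA peaks at the start of DNA replication, 33 were higher in knockdown, with a median difference of 0.39. One passed over all genes, CDCA7, a chromatin regulator and MYC target, which rose 1.67-fold from 2191 ± 309 to 3653 ± 239 normalised reads (call lost in 4 of 17 alternatives), and 17 rose when adjusted over the list alone. Of 45 cytosolic ribosomal protein genes 43 were higher, with a median of 0.39 and none passing singly, either over all genes or adjusted over the list alone. Ribosomal protein genes have many processed pseudogenes, so single values are uncertain. Of 24 cholesterol synthesis genes 22 were higher (median 0.38). In that list 6 rose, and 10 when adjusted over the list alone. They included FDPS, farnesyl diphosphate synthase (1.58-fold, from 2171 ± 543 to 3439 ± 133 normalised reads), MVK, mevalonate kinase (1.57-fold), and SREBF2, the transcription factor that drives this pathway (1.54-fold). FDPS lost its call in 10 of 17 alternatives, SREBF2 in 9 and MVK in 6. Nuclear-encoded respiratory chain genes were higher in 30 of 33 cases (median 0.23). In that list 3 rose, with the same count adjusted over the list alone, namely UQCRH (1.53-fold), COX5B (1.53-fold) and COX7B (1.43-fold), which lost their calls in 4, 6 and 8 of 17 alternatives.

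These 4 lists stood apart from the other genes in limma's camera with its preset correlation (adjusted p = 4.2e-09 for G1/S, 4.2e-09 for ribosomal proteins, 1.11e-06 for cholesterol synthesis and 0.00015 for the respiratory chain). None held with an estimated correlation between their members (adjusted p = 0.753 for each). The library WT 3 had the lowest score of all 6 libraries in each of the 4 lists, and without it their medians were 0.27, 0.26, 0.33 and 0.19 in the same order. Other libraries stood apart too. WT 1 scored 0.09 in G1/S, near knockdown 3 at 0.14. Knockdown 2 scored 0.02 for ribosomal proteins against 0.20 and 0.32 in knockdown 1 and 3, 0.02 for cholesterol synthesis against 0.25 and 0.31, and −0.03 for the respiratory chain against 0.19 and 0.17. The G2/M list, genes of late cell cycle and mitosis, did not follow. Of its 39 measured genes, none passed over all genes or adjusted over the list alone, 23 were higher and the median was 0.06 (camera adjusted p = 0.315), though without WT 1 the median was 0.20 and the list passed (adjusted p = 0.00175).

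**Figure D2:**
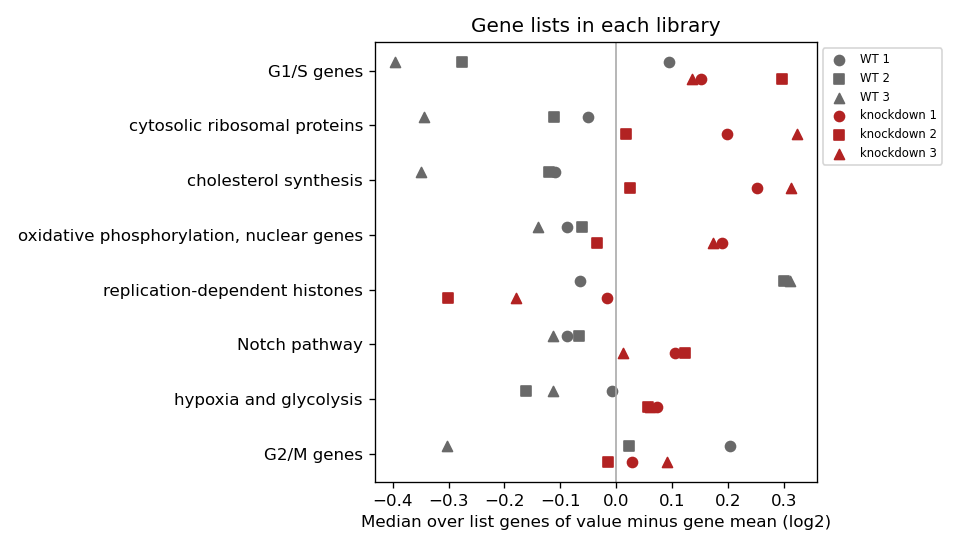
Score of each gene list in each library, the median over the list's genes of the value minus the gene's mean over the 6 libraries (horizontal axis, log2). WT 3 is lowest in the first 4 lists, and the G2/M list shows no separation of the groups.

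Another 3 lists passed camera with the preset correlation and also lost the call with an estimated one (adjusted p = 0.753 for each). All 6 measured replication-dependent histone genes were lower (median −0.30, camera adjusted p = 0.00596), and 1, HIST1H1C, fell over all genes, with 2 falls adjusted over the list alone. The groups overlapped in this list's score, which was −0.06, 0.30 and 0.31 in WT 1, 2 and 3 and −0.02, −0.30 and −0.18 in knockdown 1, 2 and 3. These mRNAs lack a poly(A) tail, their genes share near-identical copies, and of 32 listed 23 were in the table. Of 17 Notch pathway genes 14 were higher (median 0.11, camera adjusted p = 0.0416). In that list 2 rose, and 4 when adjusted over the list alone. The 2 were the ligand JAG1 (2.22-fold, from 174 ± 45.7 to 386 ± 114 normalised reads) and the target HEY1 (1.45-fold, from 1082 ± 38.3 to 1572 ± 56.5). Of 27 hypoxia and glycolysis genes 20 were higher (median 0.14, camera adjusted p = 0.0416). PDK1, which inhibits pyruvate dehydrogenase, rose 1.74-fold and PFKL, a phosphofructokinase, 1.39-fold, while ALDOC, an aldolase on the long arm of chromosome 17, fell 2.65-fold, with the same counts adjusted over the list alone. PFKL lost its call in 13 of 17 alternatives, PDK1, JAG1 and HEY1 in 5 each, and ALDOC in 6 of 15. Notch and hypoxia both lost the call with quantile normalisation (adjusted p = 0.0565 and 0.0725), without knockdown 1 (0.0830 and 0.0633), without knockdown 2 (0.0956 and 0.149) and with library weights (0.132 and 0.0588). Notch also lost it without WT 1 (0.110), with the stricter filter (0.0729) and without the long arm of chromosome 17 (0.0590), and hypoxia without WT 2 (0.148) and with the replicate number as a block (0.0659).

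Lists chosen for the study's question gave mixed results. Of 17 reported Musashi-1 target mRNAs 2 rose, JAG1 and EIF4EBP2, a repressor of translation initiation (1.74-fold, from 3504 ± 439 to 6109 ± 971 normalised reads), none fell and the median was 0.01. Adjusted over the list alone 2 rose and 2 fell. The list did not differ from other genes (camera adjusted p = 0.756). Neural stem and progenitor genes had no called member of 14 in either count (median 0.08, adjusted p = 0.798). Among 31 DNA repair and cisplatin response genes, MGMT, the enzyme that removes alkyl groups from guanine, fell 4.82-fold from 210 ± 67.9 to 43.5 ± 18.3 normalised reads (−1.24, SE 0.20, limma adjusted p = 0.0116, and 0.0594 without knockdown 1). XRCC3, a homologous recombination factor, rose 1.51-fold, as did FANCD2 of crosslink repair (1.45-fold), which was named after its value was seen. XRCC3 lost its call in 6 of 17 alternatives and EIF4EBP2 in 3. Adjusted over the list alone 3 rose and 1 fell, and the list as a whole did not pass (median 0.06, adjusted p = 0.323). None of 18 cyclins, CDKs and CDK inhibitors passed over all genes, and adjusted over the list alone 5 rose and 1 fell (median 0.22, adjusted p = 0.104, and 0.0122 with no filter). None of 25 p53 targets (median 0.13, adjusted p = 0.315) and none of 20 apoptosis regulators (median 0.05, adjusted p = 0.798) passed in either count. Without WT 3 the p53 list had a median of 0.21 and passed (adjusted p = 0.0442).

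Medulloblastoma subgroup genes moved both ways. In the Group 3 signature PDE6H, a cone photoreceptor subunit, rose 2.43-fold and NPR3, a natriuretic peptide receptor, fell 1.68-fold from 13052 ± 1708 normalised reads, with 13 measured (median −0.17, camera adjusted p = 0.617). Adjusted over the list alone 2 rose and 2 fell, and without WT 3 the median was −0.46 and the list passed (adjusted p = 0.0442). In the Group 4 signature SNCAIP (2.35-fold) and LHX2 (2.15-fold) rose, with 6 measured (median −0.35, adjusted p = 0.698), while 2 rose and 4 fell adjusted over the list alone. Of 17 alternatives, NPR3 lost its call in 7, LHX2 in 6, and PDE6H and SNCAIP in 2 each. MYC target genes did not move as a group (30 measured, POLR1B fell 1.43-fold but lost its call in 11 of 17 alternatives, median −0.0015, mean 0.0018, adjusted p = 0.944), and none passed adjusted over the list alone. Neither hedgehog genes (13 measured, median 0.13, adjusted p = 0.315) nor Wnt genes (13 measured, median −0.09, mean 0.01, adjusted p = 0.798) had a call over all genes, and adjusted over the list alone 1 Wnt gene rose. Among receptor tyrosine kinase and MAPK feedback genes KIT rose 2.77-fold and EGFR fell 2.48-fold from 148 ± 37.7 to 59.7 ± 0.67 normalised reads, and 18 of 24 were lower (median −0.19, adjusted p = 0.0958). EGFR lost its call in 7 of 16 alternatives and KIT in none of 17. Adjusted over the list alone 1 rose and 4 fell, and the list passed without WT 1 (median −0.26, adjusted p = 0.0154) and with library weights (median −0.20, adjusted p = 0.0482). In the TGF-beta and SMAD list BMP7 rose 1.98-fold, in both counts the 1 call among 22 measured, lost in 4 of 17 alternatives (median 0.0003, adjusted p = 0.852).

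Neuronal and matrix lists had single movers. In axon guidance EPHA4 rose 2.25-fold, and SEMA3A and SEMA3C, the latter named after its value was seen, fell, with 24 measured (median −0.18, camera adjusted p = 0.291, and 1 rise and 4 falls adjusted over the list alone). Among 17 synaptic genes 2 rose, among them RAB3A of synaptic vesicles (1.63-fold, call lost in 8 of 17 alternatives), and 12 were lower (median −0.18, adjusted p = 0.685). The count of 2 was the same adjusted over the list alone. None of 11 neuronal differentiation genes passed over all genes, and adjusted over the list alone 1 rose and 2 fell (median 0.07, adjusted p = 0.852). Of 28 mesenchymal and matrix genes 4 fell and none rose. CDH2 and THBS1, thrombospondin 1 (2.51-fold, from 2734 ± 815 to 1089 ± 327 normalised reads), were joined by the laminin chains LAMA1 and LAMC1, named after their values were seen (median −0.09, adjusted p = 0.315, and 7 fell and 1 rose adjusted over the list alone). EPHA4 lost its call in 2 and THBS1 in 3 of 17 alternatives. Without WT 3 the synaptic list (median −0.50, adjusted p = 0.0165) and the mesenchymal list (median −0.15, adjusted p = 0.0429) passed.

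Stress lists stayed short of the threshold. The unfolded protein and amino acid list (24 measured, median −0.03, adjusted p = 0.798) held PHGDH and SHMT2 of serine and glycine metabolism, which rose 1.66-fold and 1.49-fold (calls lost in 5 and 8 of 17 alternatives). HSPA4L of the heat shock list (13 measured, median −0.19, adjusted p = 0.278) fell by 0.53 on the log2 scale, a call lost in 8 of 17 alternatives, and FOS of the immediate early list (19 measured, median −0.12, adjusted p = 0.594) fell 1.78-fold, a call lost in 5 of 17 alternatives. None of 11 interferon response genes (median 0.15, adjusted p = 0.315) and none of 5 antigen presentation genes (median −0.25, adjusted p = 0.126) passed over all genes. In the small RNA pathway TNRC6A fell 1.41-fold, a call lost in 12 of 17 alternatives, with 13 measured (median −0.06, adjusted p = 0.736), and none of 29 splicing factors passed (median 0.05, adjusted p = 0.594). Adjusted over the list alone, 2 rose and 2 fell in the unfolded protein list, 1 rose and 2 fell in the heat shock list, 1 rose and 1 fell among interferon genes, 1 fell in each of the immediate early, antigen presentation and small RNA lists, and no splicing factor passed. Without WT 3 the heat shock list (median −0.27, adjusted p = 0.0442) and the antigen presentation list (median −0.43, adjusted p = 0.0429) passed.

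Markers of other cell types gave no common direction. Of 6 oligodendrocyte lineage markers 2 fell, among them MYRF, a myelin transcription factor (1.85-fold, from 3976 ± 682 to 2147 ± 280 normalised reads), with a list median of −0.03 (camera adjusted p = 0.308). MYRF lost its call in 4 of 17 alternatives. Of 7 astrocyte markers only ALDOC fell (median −0.20, adjusted p = 0.315). Fibroblast and endothelial markers had no call among 6 (median −0.18, adjusted p = 0.599), and neither had the 4 measured epithelial markers (median 0.18), which were too few for the list test. No myeloid or lymphoid marker passed the filter, and mitochondrially encoded genes were not analysed here. The counts adjusted over the list alone were the same in each of these lists.

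The falls were concentrated on the long arm of chromosome 17, a feature chosen after the data were seen. The chromosome was split at the widest gap between measured genes, 21428381 to 27294076. Of 578 genes beyond that gap 514 (88.9%) were lower in knockdown, with a median difference of −0.33, and 89 fell while none rose. In the recovered reads their median level in knockdown was 75.7% of WT. The 210 genes before the gap had a median of 0.01, with 2 falls and 4 rises. The falls were EPN2 and MEIS3P1 and the rises included RTN4RL1, SREBF1 and KCNJ12, all named after their values were seen. The 10 genes starting between 20 and 25 Mb, before the gap, had a median of −0.29. The remaining 12770 genes had a median of 0.02, with 223 falls and 238 rises. Every library kept its group's side, with long-arm scores of 0.15, 0.17 and 0.15 in WT and −0.13, −0.19 and −0.17 in knockdown. The long arm held 28.3% of all falls (Fisher's exact test, two-sided, odds ratio 10.3, 95% interval 7.84 to 13.5, p = 2.9e-49, over genes, which are not independent replicates). Without these genes 191 genes rose and 184 fell.

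**Figure D3:**
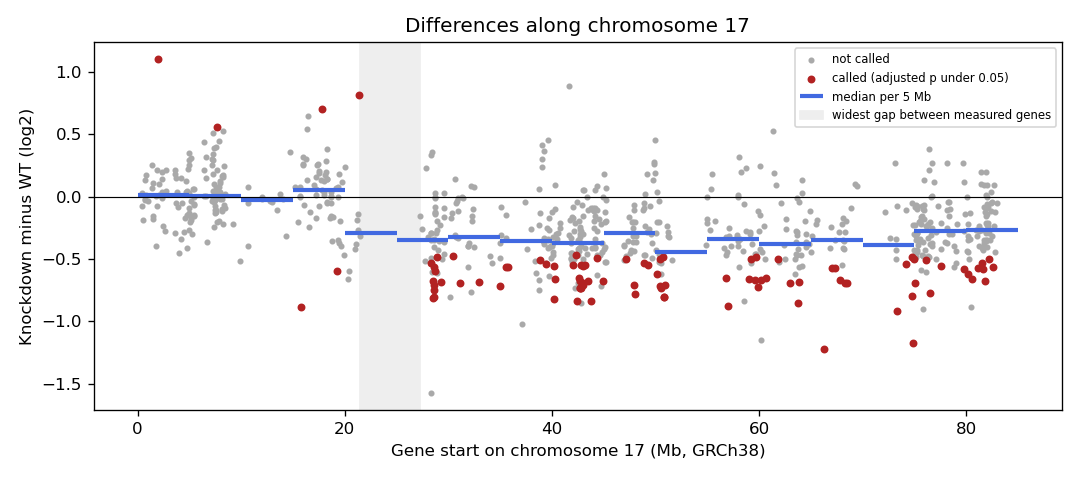
Knockdown minus WT difference (vertical axis, log2) of each measured gene against its start on chromosome 17 (horizontal axis, Mb, GRCh38), with called genes in red and medians per 5 Mb as blue lines. The medians lie between −0.03 and 0.05 up to 20 Mb and between −0.27 and −0.44 beyond it.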

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

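Tests on the recovered reads, on length and GC, and without the long arm of chromosome 17 were chosen after seeing the data. No result turned its direction past the threshold in any alternative run. MSI1 did not pass in any of them, and its difference ranged from −0.28 (without WT 3) to −0.17 (without knockdown 2). Library weights raised the calls to 532 higher and 681 lower. Leaving out 1 library gave 25 to 329 higher genes, 31 to 397 lower genes, 42 to 106 genes with a difference of at least 1, and 5 to 13 lists. The lowest counts of genes came without knockdown 1 and the highest without WT 1. The total was 56 without knockdown 1, 126 without knockdown 2, 92 without knockdown 3 and 204 without WT 2, against 556, and without WT 3 the higher genes fell to 160 while 13 lists passed. Of those totals 55, 117, 90 and 184 were among the 556. The cause was not tested. Without knockdown 1, 41 of the genes taken by the naming rule lost their call, against 8 without WT 1. Limma voom on the recovered reads gave 220 higher and 294 lower genes, 504 of them shared with the main calls, and 187 with a difference of at least 1, since its log scale does not compress low counts. A minimum difference of 0.5 (treat) left 0 higher genes and 1 lower gene, S100A6 (difference −1.97, adjusted p = 0.00598), named after its value was seen and below the level the naming rule asks for. Camera with an estimated correlation and directional fry each left 0 of the 7 lists, while fry for change in either direction passed 18. With 6 libraries the estimated correlation leaves camera little power, so its loss of the lists decides little. Without the long arm of chromosome 17, 184 genes fell and 191 rose, with 6 lists, against 225 falls and 242 rises outside that arm in the fit of all genes. The arm's own falls are in neither pair of counts, and all 375 genes still called were among the 556. Leaving out the arm, with 15.4% of its genes called against 3.61% on other chromosomes, makes the adjustment stricter for the rest. No other cause of the loss was tested. Replicate numbers did not pair the libraries, since same-numbered libraries correlated in their deviations with r of −0.005, −0.25 and 0.005. With the replicate block 101 genes rose and 120 fell, 214 of them among the 556, and 23 of the genes taken by the naming rule lost their call. Setting library medians equal moved the share of rises among calls from 43.5% to 38.9%. The other filters, scalings and variance models and the length and GC regression left each count within 1.5 times. At 17299671 to 38790342 reads and 3 libraries per group, 12% of simulated 1.5-fold changes were recovered, so small changes may largely be missed. The simulation called 120 genes against 556 here, so the recovery in the real data may differ. No pseudocount was needed on this scale.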

Other observations

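All tests in this part were run on the same data that showed the patterns. Those on MSI1, on other splits, and the follow-up tests on chromosome 17 and on other chromosomes were chosen only after the result was seen. The tests for a chromosome change, for 3' UTR sites and motifs, and for the 4 lists were written before their result was seen.

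Besides the long arm of chromosome 17, windows of 50 neighbouring genes elsewhere stood out less. The lowest lay on chromosome 7, starting at 107742817, with a median difference of −0.28 and 5 falls. The highest lay on chromosome 1, starting at 2425980, with 0.24. The largest median size of any window in the other splits of the libraries was 0.209. That size was taken over all chromosomes, chromosome 17 included, and each other split mixed both groups on each side. The long arm of chromosome 17 as a whole reached 0.148 in those splits. The value of 0.209 is thus no clean measure of chance for windows elsewhere.

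MSI1 mRNA at 85.2% of WT is a small loss for libraries labelled knockdown. A single library under the wrong label is argued against, since 0 of the 6 libraries correlated best with a library of the other group, but an exchange of the 2 whole groups would give the same 0 and was not tested by it, though MSI1 lay in the direction of the labels. Too few reads do not account for it, because the lower bound of the interval is 72.2% of WT. Reads from a copy counted as MSI1 cannot be told apart, as the table had 0 rows for MSI pseudogenes and the counting is not given in the sources used here. A loss of protein without a matching loss of mRNA, or a knockdown that had faded by harvest, may also stand behind it and was not tested.

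Of the called genes, 89 falls lie on the long arm of chromosome 17, and the test for a subclone with a gained or lost chromosome, a median beyond 0.2 over a whole chromosome, was met by chromosome 17 alone with −0.239. A candidate explanation is therefore that the knockdown cells carry fewer copies of the long arm than the WT cells. The level of 75.7% of WT is about what 3 copies against 4 would give. The border would lie on the short arm near the centromere. Copy number was not measured, so neither the number of copies nor the kind of change can be told from these values. A trend with length or GC (median −0.336 after regression) and 1 odd library (0 on the wrong side) are excluded by these values. No other chromosome exceeded −0.0981 in size, so at the cut of 0.2 the 467 calls elsewhere have no such whole-chromosome account. Medians on chromosomes 4, 7 and 9 (−0.098, −0.096 and 0.089) were still beyond the other splits (0.072, 0.068 and 0.058). Some were not, such as −0.018 on chromosome 5 (0.040). Smaller copy changes, or changes in part of a chromosome, thus stay open. For all calls, the lowest z of 7-base 3' UTR sites, −4.4, lay within the −6.8 reached by other splits. Both tails of the other splits were counted, but only the lower tail of the real one, whose highest z was 7.61. No site of lower genes stood out on this unequal measure. The change per UAG motif per kb, 0.000381, lay within the 0.00132 of other splits. With a median of 11.2 UAG motifs per kb, this count can hardly tell bound mRNAs from others, so it does not decide on Musashi motifs. Loss of MSI1, drift of the cultured cells and any construct are confounded with the groups. The real split called 556 genes and the highest of the other 9 called 0, but 10 splits are too few for a share under 0.05. Each other split also mixed both groups on each side, so a group difference widened its spread and favoured few calls.

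G1/S, ribosomal protein, cholesterol synthesis and respiratory chain genes were higher together, with a median of their 4 medians of 0.39. WT 3, the lowest library, is not the whole cause, since 0.263 remained without it, although it adds to the size. Length and GC content (0.349 after regression) and expression level (0.36 after subtracting genes of like level) left most of the shift. A difference in growth state or density at harvest, or the knockdown itself, stays open and was not tested. The estimated correlation between members was 0.71, 0.59, 0.32 and 0.29 in the same order of lists. Hypoxia and glycolysis, at −0.005, lost its call too, with an unadjusted camera p of 0.0083 at the preset correlation and 0.0415 with the estimated one. A correlation above the preset 0.01 thus cannot be the reason in that list. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries rather than from the genes, which leaves it little power. The lost calls therefore do not decide whether these lists moved. The higher G1/S genes may reflect more cells at the start of S phase, but the G2/M list had a median of 0.06, or 0.20 without WT 1. The replication-dependent histone genes went the other way, with all 6 measured lower in knockdown (median −0.30). Their scores overlapped between the groups and their mRNAs lack a poly(A) tail, so they do not decide it either.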
